A study of Homo sapiens with 6 samples.

How the data were processed

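RNA-seq was performed on LNCaP cells, an androgen-sensitive human prostate carcinoma line. All 6 libraries came from cells kept on enzalutamide, an antiandrogen drug, at 10 uM for 72 h. In 3 libraries the cells carried a control guide (sgControl) and in 3 a guide against PRKCI (sgPRKCI), which encodes the atypical protein kinase C iota. Groups and replicate numbers were taken from the labels. Nothing in the labels said that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

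The deposited values were a gene-level signal, namely read counts that the authors had divided by a size factor per library, with 18081 genes and a column per library. Per the submitters' processing notes, STAR and DESeq2 were used with the GRCh38 build. Their versions, the annotation, the gene filter, the strand setting of the counting and the treatment of multiply mapped reads were not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical gene copies, therefore could not be told apart. Such overlaps are named below for some genes only. Within each column every value was a whole multiple of a single step: 100% of values came out whole within a tolerance of 0.01 reads. Dividing by the step gave totals from 7670166 to 12391831 reads per library. In sgControl 3 the step was 0.997, too close to 1 for an independent check of the recovered reads, so edgeR and DESeq2 left that library out and used the other 5. Its read total, and the group read totals, counting intervals and floors given for single genes, do use the reads recovered from it. Counting intervals and floors (3 reads per library) cover counting error only, since reads without molecular identifiers are not independent molecules.

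Genes with a normalized count of at least 10 in at least 3 of the 6 libraries were tested (14793 genes). Values were transformed as log2(normalized count + 1). Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment over all tested genes, at a threshold of 0.05. The design had been planned for normalized values and was fitted as planned, with no block. Fold changes are on the log2(normalized count + 1) scale, which understates the change of genes near 0. Positive values mean higher in sgPRKCI. Two-sided tests were used throughout.

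Before the data were examined, 36 gene lists were fixed, covering translation, androgen response, lineage, TGF-beta, polycomb, metabolism, cell cycle, stress and markers of other cell types. Lists with at least 5 tested members (35) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in a single direction, were alternatives. The fibroblast and stromal list had 4 tested members and was not tested.

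Named genes followed a rule also fixed before the data were examined. It took 15 genes chosen in advance where measured, the 10 largest rises and 10 largest falls among called genes with a mean of at least 100 and non-overlapping groups, and up to 3 called members per direction of each list described, those with the smallest adjusted p. Clone-based, LOC, LINC, antisense, pseudogene, microRNA and snoRNA names were left out of the second part. Of the genes chosen in advance, TGFB2 was not analysed here and CHGA was below the filter, at 0 to 5.50 normalized counts per library. Some genes that the rule takes are not reported here. Genes outside the rule are marked as chosen after their values were seen.

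Symbols were matched to GENCODE release 29 on GRCh38 for positions (18058 of 18081 genes matched, 14777 of 14793 tested). The annotation the authors used may differ. All coordinates are 1-based.

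Libraries of the same group differed by more than sampling noise (chi-square per gene from 2.31 to 3.27 over genes with at least 20 reads in the pair), and libraries of different groups by 13.9 to 19.75, so no library was treated as a duplicate.

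The tests were tried on simulated data with the same genes, group sizes and depths, in which a random set of genes was changed by known folds. In this comparison limma tested 14769 simulated genes and recovered 36.7% of genes changed 1.25-fold, 76.0% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold, with 4 false calls. Camera recovered the 1 list that had been moved and called 0 of 19 unmoved lists. Simulated genes were drawn independently of each other, with the same dispersion for every gene. The simulation therefore cannot tell how often camera calls unmoved lists whose genes are correlated.

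Alternatives included other pseudocounts, no filter and a mean count of at least 50, TMM factors, quantile normalization, no trend, a replicate block, leaving out each library in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads of 5 libraries. A correction for GC content and transcript length, and a run without chromosome 18 and 13q12, were added after the data had been seen.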

Results

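Expression of 18081 genes was measured by RNA-seq in LNCaP cells, an androgen-sensitive line from a prostate carcinoma. All cells had been kept on enzalutamide, an antiandrogen drug, at 10 uM for 72 h. The 3 sgControl libraries held 10167647, 10574313 and 9354113 reads in genes and the 3 sgPRKCI libraries 12391831, 7670166 and 8908963, as recovered from the normalized counts. The only comparison of the design was sgPRKCI against sgControl, both under enzalutamide. It asks which transcripts differ once the atypical protein kinase C iota gene is targeted, in a study concerned with EZH2 and translation in enzalutamide resistance. Values below are mean normalized counts ± SD (n = 3 libraries per group), and adjusted p-values are from limma.

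Under enzalutamide, sgPRKCI cells had lower transcripts of the ATF4 amino acid response and the unfolded protein response and higher transcripts of cytosolic ribosomal proteins than sgControl cells. Of 32 tested ATF4 amino acid response genes, 30 fell and 0 rose, with a median log2 fold change of -0.96. Of 79 cytosolic ribosomal protein genes, 76 rose and 0 fell, with a median of 0.39, but that list's call was lost with an estimated correlation (camera adjusted p = 0.1896, against 0.00479 for the ATF4 and 0.00783 for the unfolded protein response list). KLK3, the gene of prostate-specific antigen, was higher, and EZH2 was lower, a call lost without a trend in the variance model (adjusted p = 0.0873) and with DESeq2 (adjusted p = 0.161). Transcripts with the largest shifts included MMP16, NOVA1 and EPHA3 among the falls and CXCL9, HYCC1 and TNFRSF19 among the rises.

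The targeted gene was checked first. PRKCI (ENSG00000163558, GRCh38 chromosome 3, 170222365 to 170305981) stood at 602, 650.1 and 712 normalized counts in the sgControl libraries and at 435, 479 and 465 in the sgPRKCI libraries. The fall was 1.42-fold (log2 fold change -0.51, SE 0.0718, adjusted p = 1.43e-07), with every sgPRKCI library below every sgControl library. Transcript was therefore still measured in the targeted cells. PRKCZ, which encodes the related atypical kinase zeta, stood at 710.4 ± 17.1 in sgControl and 668 ± 59.4 in sgPRKCI (log2 fold change -0.09, adjusted p = 0.322). Over a list of 18 atypical PKC and polarity genes, 4 fell, 1 rose and 13 did not pass the test (camera adjusted p = 0.272). Besides PRKCI, those that fell included SQSTM1, a PKC-binding autophagy receptor (log2 fold change -0.45), and LLGL2, a basolateral polarity protein (-0.33). PARD6G, a partner of atypical PKC on chromosome 18, rose (0.61). SQSTM1 overlaps MGAT4B and MRNIP on the opposite strand. PRKCZ overlaps FAAP20 on the opposite strand, which had a mean of 864.9 over all libraries against 689.4 for PRKCZ, so the PRKCZ values are uncertain.

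Across all 14793 tested genes, 4404 changed: 2123 were higher and 2281 lower in sgPRKCI. At an unadjusted p below 0.05 there were 5824. A change of at least 2-fold was seen in 525 of the called genes, 241 higher and 284 lower. The 3 libraries of each group did not overlap in 6061 genes (41.0%, where chance gives 10%). The 217 tested genes of chromosome 18 had a median log2 fold change of 0.28, with 96 higher and 10 lower. The count of calls was 2643 without a trend in the variance model and 2673 with DESeq2 on 5 libraries.

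**Figure D1:**
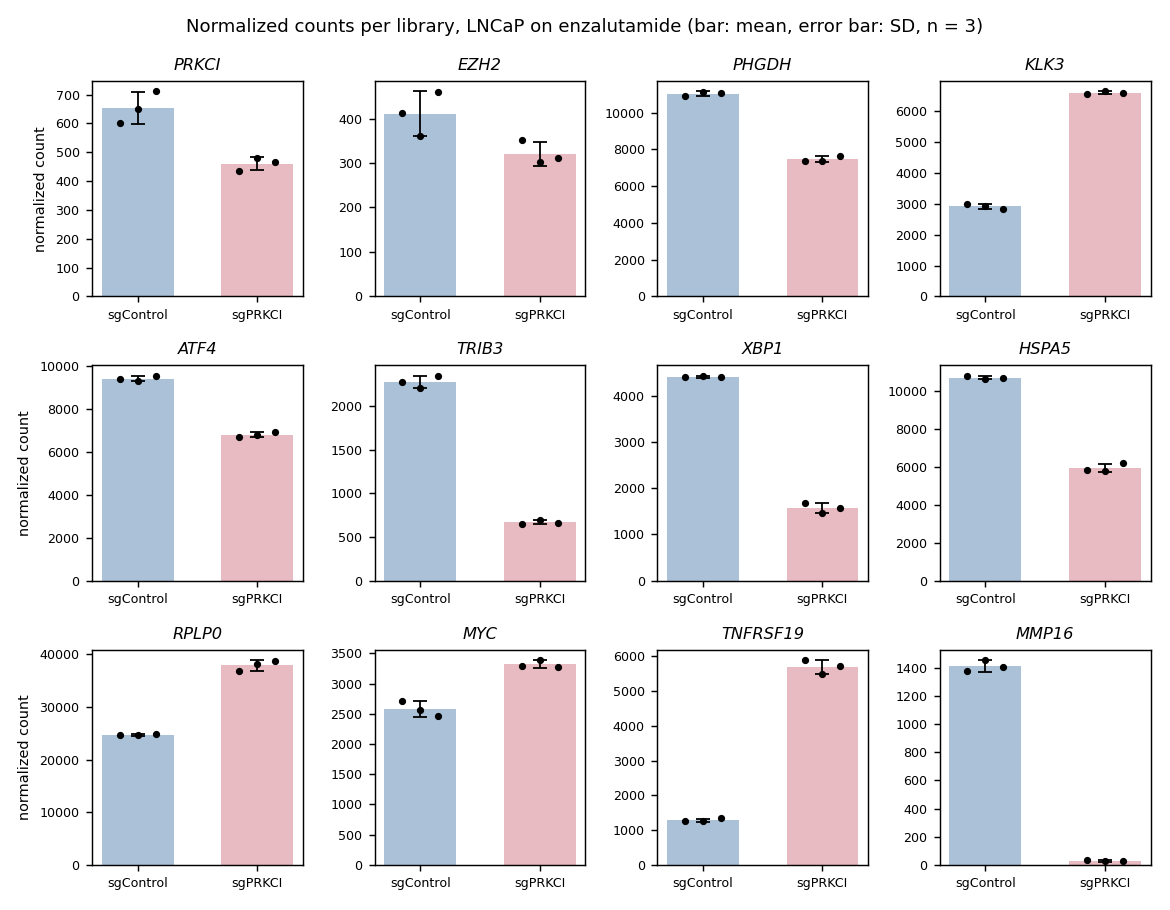
Normalized counts (y axis, linear from 0) of 12 genes in each library (points) of sgControl and sgPRKCI cells on enzalutamide, with the mean (bar) and SD (error bar) of 3 libraries per group. PRKCI fell from a mean of 654.5 to 459.9 and TRIB3 from 2275 to 669, while KLK3 rose from 2920.0 to 6608 and RPLP0 from 24690.0 to 37910.0.

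Among genes with a mean of at least 100, the largest falls were in MMP16, a membrane-type matrix metalloproteinase, which went from 1415 ± 40.6 to 28.98 ± 5.72 (47.8-fold, adjusted p = 8.92e-38), and in NOVA1, a neuronal splicing regulator, from 317 ± 23.5 to 6.79 ± 1.70 (41.3-fold). The ephrin receptor EPHA3 fell 22.9-fold, and RAB27A, a regulator of vesicle secretion that overlaps PIGB and PIGBOS1, fell 9.15-fold. TOX3, ADD3, TENM2, NIBAN1, KCNMA1 and ADGRG6 completed the 10 largest falls, at 6.06-fold for TOX3 to 4.89-fold for ADGRG6.

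Among the rises, CXCL9, a chemokine induced by interferon gamma, stood at 0.292 in sgControl, which was 1 read in 1 of 3 libraries, and at 409 ± 176 in sgPRKCI. The ratio of reads adjusted for depth was 1230, with an exact 95% counting interval of 220.3 to 48630; this uses the reads recovered from sgControl 3, which were not independently checked. HYCC1, which encodes hyccin, rose 6.54-fold from 147 ± 13.98 to 962 ± 24.1 (adjusted p = 6.79e-31), and MIOS, a subunit of the GATOR2 complex that signals amino acids to mTORC1, rose 4.53-fold. TM4SF1, ABCB11, NRIP1 (a nuclear receptor corepressor) and CHI3L1 rose between 4.09-fold (TM4SF1) and 3.36-fold (CHI3L1). CHI3L1 was uneven in sgPRKCI, at 112, 251 and 301 in replicates 1 to 3. CXCL9 was also lowest in replicate 1, at 206, 494 and 527. The TNF receptor family member TNFRSF19 rose 4.43-fold from 1286 ± 42.4 to 5703 ± 200.5, PCOTH 5.08-fold and C1QTNF9B 4.22-fold. PCOTH overlaps C1QTNF9B and MIPEP on the opposite strand, so their reads could not be told apart. TNFRSF19, PCOTH and C1QTNF9B lie close together on chromosome 13, from 23570370 (TNFRSF19) to 23902655 (C1QTNF9B).

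Genes of the ATF4 response, which under stress induces genes for amino acid synthesis and transport and for aminoacyl-tRNA synthetases, fell together. ATF4 itself went from 9392 ± 134 to 6784 ± 121 (log2 fold change -0.47, adjusted p = 3.25e-14). In the ATF4 list 30 of 32 genes fell, also 30 when adjusted over the list alone (camera adjusted p = 1.21e-54, and adjusted p = 0.00479 with an estimated correlation). The pseudokinase TRIB3 fell 3.40-fold from 2275 ± 72.4 to 669 ± 24.0, the mTORC1 inhibitor DDIT4 fell 2.33-fold and the angiogenic factor VEGFA 2.34-fold. The unfolded protein response list had 21 of 23 genes lower and 0 higher, and 22 lower when adjusted over the list alone (camera adjusted p = 5.18e-22, and adjusted p = 0.00783 with an estimated correlation). XBP1, a transcription factor of that response, fell 2.81-fold from 4410.0 ± 20.51 to 1569 ± 113. HERPUD1, which acts in degradation of endoplasmic reticulum proteins, fell 2.16-fold, and the chaperone HSPA5 1.80-fold from 10690.0 ± 104 to 5933 ± 213.

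Of 22 cytosolic aminoacyl-tRNA synthetases, 10 fell, 1 rose and 11 did not pass the test (camera adjusted p = 1.69e-08, but adjusted p = 0.211 with an estimated correlation); over the list alone 10 fell and 2 rose. GARS1, SARS1 and WARS1 had log2 fold changes of -0.97, -0.91 and -1.04, and QARS1 rose by 0.42. In serine, glycine and folate-linked metabolism 8 of 18 genes fell and 3 rose, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.000451, but adjusted p = 0.1896 with an estimated correlation). Of these 18 genes, 5 also belong to the ATF4 list. PHGDH, which opens serine synthesis, fell from 11040.0 ± 129 to 7481 ± 161 (log2 fold change -0.56, adjusted p = 5.20e-17). PSAT1, MTHFD2 and SHMT2 fell by 0.97, 0.91 and 0.66 on the log2 scale. AHCY (0.29), TYMS (0.36) and MTHFD1 (0.16) rose, and the MTHFD1 call was lost without sgControl replicate 1 (0.14), without sgControl replicate 2 (0.14) or without sgPRKCI replicate 1 (0.12). TYMS overlaps ENOSF1 on the opposite strand and lies on chromosome 18.

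**Figure D2:**
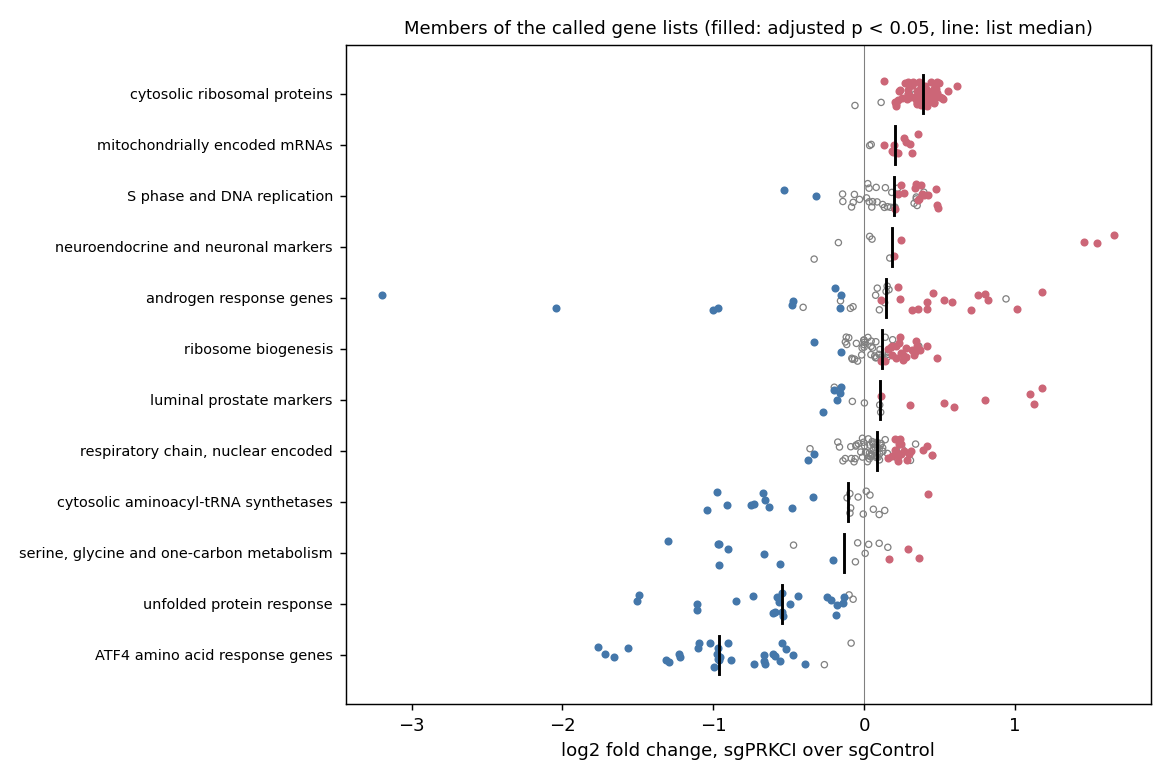
Log2 fold change of sgPRKCI over sgControl (x axis) of each tested member (points) of the 12 called gene lists (y axis). Filled points passed an adjusted p of 0.05, red higher and blue lower, open points did not, and the vertical line is the list median, from -0.96 for ATF4 response genes to 0.39 for cytosolic ribosomal proteins. The median of the mitochondrially encoded mRNAs, 0.21 here, was -0.04 under quantile normalization.

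Ribosomal protein genes moved in the other direction. In the cytosolic ribosomal protein list 76 of 79 genes rose, or 77 adjusted over the list alone, with a median rise of 1.31-fold (camera adjusted p = 5.50e-58, but adjusted p = 0.1896 with an estimated correlation). RPLP0 rose from 24690.0 ± 169 to 37910.0 ± 1039 (log2 fold change 0.62), RPL21 by 0.52 and RPL6 by 0.50. Ribosomal protein transcripts made up 8.35% to 8.74% of normalized counts in sgControl libraries and 10.5% to 10.9% in sgPRKCI libraries. Many of these genes have near-identical pseudogene copies, so their single values are uncertain. Of 61 ribosome biogenesis genes, 23 rose and 2 fell, or 24 and 2 adjusted over the list alone (camera adjusted p = 0.000643, but adjusted p = 0.211 with an estimated correlation). These included the nucleolar proteins FBL (0.41), NPM1 (0.37) and NOP56 (0.33), whereas RRN3, an RNA polymerase I factor, fell (-0.33).

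Translation factors were split. Among 39 initiation factors 14 rose and 8 fell (17 and 9 adjusted over the list alone, camera adjusted p = 0.0563): EIF4B, EIF3E and PABPC1 rose by 0.39, 0.44 and 0.36, and EIF1, EIF2S2 and EIF4H changed by -0.38, -0.41 and -0.26. EIF4B overlaps TNS2-AS1 on the opposite strand. Among 17 elongation and release factors 7 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.0509). EEF1A1 (0.36) and EEF2 (0.30) were higher with the deposited scaling but showed a log2 fold change of 0 under quantile normalization, which fixes the values of the most abundant genes. EEF1B2 rose by 0.31 and the release factor GSPT1 fell (-0.29). Mitochondrial ribosomal proteins had 7 of 76 genes higher and 4 lower, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.385), with MRPS25 (0.42) the call with the smallest p. MRPS25 overlaps NR2C2 on the opposite strand. MYC, a transcription factor that drives ribosome production, rose from 2581 ± 127 to 3320.0 ± 64.6 (log2 fold change 0.36, adjusted p = 4.75e-09).

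KLK3 (chromosome 19, 50854915 to 50860764) rose 2.26-fold from 2920.0 ± 81.3 to 6608 ± 42.9 (adjusted p = 1.13e-28). Among 37 androgen response genes 16 rose and 9 fell, or 17 and 9 adjusted over the list alone (camera adjusted p = 0.0355, but adjusted p = 0.211 with an estimated correlation). This call was lost without sgPRKCI replicate 3 (adjusted p = 0.0572) and without a trend in the variance model (adjusted p = 0.0868). KLK2 and CAMKK2 rose by 0.80 and 0.59. TSC22D3, which glucocorticoids also induce, fell 2.00-fold. UGT2B15, an enzyme that inactivates androgens and belongs to a family of near-identical genes, fell 4.12-fold. The list test took no account of whether androgens raise or lower a member, so its counts give no direction of androgen signalling. TMPRSS2 and FKBP5, both classical targets, had log2 fold changes of 0.08 and 0.10 that did not pass the test (adjusted p = 0.424 and 0.283).

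Of 18 luminal prostate markers, 8 rose and 5 fell, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.0474, but adjusted p = 0.433 with an estimated correlation). That call was also lost without sgControl replicate 3 (adjusted p = 0.0523), sgPRKCI replicate 1 (0.0629) or sgPRKCI replicate 2 (0.0903), and under 3 further settings. KLK3 and KLK2 were among the rises, and CDH1 (-0.18) and KRT8 (-0.15) fell. KRT8 overlaps KRT18 on the opposite strand. Of 5 tested basal markers, 3 rose and 0 fell (the same counts adjusted over the list alone, camera adjusted p = 0.187), with JAG2 at 0.28. Neuroendocrine and neuronal markers had 5 of 10 tested genes higher and 0 lower, with the same counts over the list alone (camera adjusted p = 0.00384, but adjusted p = 0.211 with an estimated correlation and 0.0662 without the genes of chromosome 18 and 13q12). The list held 33 markers, of which 16 were in the data and only these 10 passed the filter. SYT4, a synaptotagmin on chromosome 18, rose 2.74-fold from 1893 ± 85.1 to 5187 ± 180, PEG10 2.91-fold from 37.3 ± 16.1 to 105 ± 25.5, and the neurofilament gene NEFL 3.15-fold from 19.4 ± 5.84 to 61.9 ± 9.52. ENO2, a neuronal enolase, rose by 0.25 (adjusted p = 0.0238), a call lost without sgControl replicate 3 (0.20), sgPRKCI replicate 1 (0.24) or sgPRKCI replicate 2 (0.22). Synaptophysin (SYP) stood at 40.7 ± 4.55 and 43.0 ± 11.7 (adjusted p = 0.908).

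EZH2 (chromosome 7, 148807383 to 148884321), the catalytic subunit of polycomb repressive complex PRC2, went from 411 ± 50.2 to 321 ± 26.9 (log2 fold change -0.35, adjusted p = 0.00164), a call lost without a trend in the variance model and with DESeq2. Among 12 PRC2 subunits 4 rose and 2 fell, also over the list alone (camera adjusted p = 0.270). RBBP7 (0.40), PHF19 (0.46) and the EZH2 paralog EZH1 (0.35) rose, and EPOP (-0.52) fell. Among 24 tested developmental polycomb targets 3 rose, 3 fell and 18 did not pass the test, also over the list alone. Their median was -0.03, their mean 0.18 and the direction of the test up (camera adjusted p = 0.691). CCND2, which encodes cyclin D2, rose from 11.8 ± 5.02 to 66.2 ± 11.2, while HOXB9 fell 2.33-fold.

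TGFB1 stood at 302 ± 42.7 and 305 ± 29.3 (adjusted p = 0.916) and overlaps HNRNPUL1 on the opposite strand. Of 30 TGF-beta response genes 6 rose and 7 fell, also over the list alone (camera adjusted p = 0.541). THBS1 and CCN1 rose by 0.64 and 0.65, and FN1, COL1A1 and CDKN1A changed by -0.67, -0.60 and -0.55. Of 18 epithelial-mesenchymal transition genes 5 rose and 5 fell (6 and 5 over the list alone, camera adjusted p = 0.855), with a median of 0.10 against a test direction of down. Tenascin C (TNC) rose 3.29-fold from 27.8 ± 4.54 to 93.9 ± 16.3, and COL5A1 fell 3.26-fold.

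Of 45 S phase genes 15 rose and 2 fell, or 17 and 2 adjusted over the list alone (camera adjusted p = 0.00120, but adjusted p = 0.145 with an estimated correlation). The replication factors MCM4, PCNA and MCM3 rose by 0.47, 0.42 and 0.36, and EXO1 fell (-0.53). Of 41 genes of G2 and mitosis 10 rose and 5 fell (11 and 5 over the list alone, camera adjusted p = 0.520, median -0.0005, mean 0.05), with CDK1 (0.53) and CCNA2 (0.63) higher and CENPA (-0.78) and PLK1 (-0.28) lower. CENPA overlaps SLC35F6 on the same strand. CCNA2, with a mean of 270.3 over all libraries, overlaps EXOSC9 (263.7) on the opposite strand, so its values are uncertain. Of 15 replication-dependent histone genes 1 rose and 1 fell, or 0 and 1 over the list alone (camera adjusted p = 0.855, median 0.03, mean -0.07).

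Mitochondrially encoded mRNAs had 11 of 13 genes higher and 0 lower, also over the list alone (camera adjusted p = 1.97e-05, but adjusted p = 0.433 with an estimated correlation and 0.115 with fry). The median of 0.21 became -0.04 under quantile normalization (adjusted p = 0.543). Mitochondrial transcripts took 7.25% to 7.89% of normalized counts in sgControl and 8.04% to 9.57% in sgPRKCI libraries. Of 74 nuclear-encoded respiratory chain genes 20 rose and 2 fell, also over the list alone (camera adjusted p = 0.00473, but adjusted p = 0.433 with an estimated correlation and 0.135 after correction for GC content and length). COX6B1 and ATP5MC1 rose by 0.39 and 0.42, and CYC1 changed by -0.37. In glycolysis 5 of 20 genes rose and 6 fell (6 and 6 over the list alone, camera adjusted p = 0.718, median 0.06, mean -0.05), and the lactate transporters SLC16A3 (-0.63) and SLC16A1 (-0.53) were among the falls. SLC16A3, with a mean of 967.6 over all libraries, overlaps CSNK1D (3222) on the opposite strand, so its values are uncertain. GAPDH was 0.18 higher, and -0.08 under quantile normalization. Fatty acid synthesis had 3 of 13 genes higher and 6 lower (3 and 7 over the list alone, camera adjusted p = 0.0729), with SCD at -0.36 and ACLY at -0.32. Cholesterol synthesis had 5 of 23 higher and 1 lower, also over the list alone (camera adjusted p = 0.502), with LSS at 0.27.

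In the hypoxia list 3 of 23 genes rose and 6 fell, also over the list alone (camera adjusted p = 0.270), among them VEGFA and NDRG1 (-0.48). Of 24 p53 targets 5 rose and 6 fell, also over the list alone (camera adjusted p = 0.385, median 0.05, mean -0.13 and a test direction of down); SESN2 (-1.56) and GDF15 (-0.84), which ATF4 also induces, were among the falls. Of 18 immediate early genes 4 rose and 4 fell, also over the list alone (camera adjusted p = 0.855), with KLF4 at 0.96 and ATF3 at -1.10. Of 32 proteasome subunits 5 rose and 7 fell, also over the list alone (camera adjusted p = 0.574, median -0.03, mean 0.0031), with PSMD8 at -0.26.

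Camera called none of the following immune-related lists, while fry, which does not compare a list with other genes, called the type I interferon response (adjusted p = 0.0263) and the NF-kB response genes (adjusted p = 0.0379). Of 25 type I interferon response genes 7 rose and 3 fell, or 8 and 3 over the list alone (camera adjusted p = 0.111). OAS3 (0.89) and PARP14 (0.60) rose, and ISG15 (-0.76) and IRF7 (-0.41) fell. Of 14 MHC class I presentation genes 3 rose and 2 fell (3 and 3 over the list alone, camera adjusted p = 0.558): the immunoproteasome subunit PSMB8 rose by 1.02 and B2M by 0.25. PSMB8 overlaps PSMB9 on the opposite strand. Of 19 NF-kB response genes 5 rose and 0 fell, also over the list alone (camera adjusted p = 0.158), with TNFAIP2 at 0.92.

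Markers of other cell types were also measured. Of 7 tested leukocyte markers 3 rose and 0 fell, also over the list alone (camera adjusted p = 0.0531). HLA-DRA went from 11.5 ± 5.35 to 74.6 ± 28.2, CD74 from 76.2 ± 19.9 to 184 ± 72.7 and LYZ from 56.5 ± 6.31 to 117 ± 62.5, the last lost without sgPRKCI replicate 3 (log2 fold change 0.50). Of 10 markers of androgen-independent prostate lines 3 rose and 2 fell, or 4 and 2 over the list alone (camera adjusted p = 0.718, median 0.17, mean -0.13). CD44 rose from 20.54 ± 3.90 to 51.1 ± 14.8 and VIM by 0.40, and LCN2 fell from 20.7 ± 9.25 to 1.40 ± 0.724. The groups overlapped for VIM, with sgPRKCI 1 at 344.8 and sgControl 3 at 349.9. CD44 was also lowest in sgPRKCI 1 of its group (34.02, then 60.99 and 58.14).

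Of the 12 called lists, 8 higher and 4 lower, only the ATF4 and unfolded protein response lists kept their call with an estimated correlation, and fry called 21 of 35 lists. With 3 libraries per group and no label that names more than 1 cell population per guide, a difference between the populations that does not come from PRKCI was not separable from the effect of the guide.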

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

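The correction for GC content and length and the run without chromosome 18 and 13q12 were chosen after the data had been seen. The number of genes changed (4404) was 2643 without a trend in the variance model (1255 genes higher in sgPRKCI, 1388 lower) and 2673 with DESeq2 on the recovered reads of 5 libraries (1325 higher, 1348 lower), of which 2479 and 2665 were shared with the 4404. DESeq2 and edgeR were run without sgControl 3, whose recovered reads could not be checked, so part of the drop comes from fewer samples: limma on those 5 libraries called 3770 and edgeR 3915. Asking for a log2 fold change of at least 1 as well left 525. Leaving out a library in turn gave 3630 to 3894 genes. Quantile normalization gave 4319 genes, 52.3% of them higher against 48.2%, and TMM factors 4407. The added alternatives gave 4571 (GC content and length) and 4273 (without chromosome 18 and 13q12). With an estimated correlation camera called 0 lists higher and 2 lower, and fry called 12 higher and 9 lower, where preset camera called 8 and 4; fry does not compare a list with other genes, and otherwise the cause was not tested. Under quantile normalization the log2 fold changes of EEF1A1, EEF2 and MT-CO1 became 0, fixed by their top ranks, and those of FASN, GAPDH and the mitochondrially encoded mRNAs became -0.026, -0.0762 and -0.0362. Among genes not called in the report, SYP became -0.0332 without sgControl replicate 3, -0.1504 without sgPRKCI replicate 3 (range 0.2164 to -0.1504 with a library left out), -0.017 with edgeR and -0.009 with DESeq2, and TGFB1 -0.09 without sgControl replicate 1 and -0.0532 without sgPRKCI replicate 3 (range -0.09 to 0.1153); the cause was not tested. The 183 called named genes gave 3254 values under alternatives, of which 3079 kept direction and call and 170 kept direction only. The other 5 did not keep direction, all under quantile normalization: FASN and GAPDH changed sign, and EEF1A1, EEF2 and MT-CO1 became 0. PRKCI kept its direction and call under every alternative run. Replicate numbers were not treated as pairing the samples, since no label says that they do. Deviations of same-numbered libraries correlated by 0.05, 0.03 and 0.03, and each library correlated best with its own number in the other group. That is a hint from the data and not the design, and values this small neither show nor exclude a shared batch. A replicate block gave 4499 genes, 4395 of them shared with the 4404. At this depth limma recovered 36.7% of the smallest simulated changes, so small changes were often missed.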

Other observations

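Tests of grouping by position, of chromosome 18 by arm, of MHC class I and of a difference between the populations were chosen after the result had been seen, as were the genes named in this part.

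Several transcripts present in sgControl cells were at or near 0 in sgPRKCI cells. UNC13C, a synaptic vesicle priming protein, stood at 107 ± 15.1 normalized counts in sgControl (343 reads over 3 libraries, here and below with the reads recovered from sgControl 3, which were not independently checked) and had 0 reads in sgPRKCI, at least 34.3-fold lower against a floor of 3 reads per library. RALYL, an RNA-binding protein of the nervous system, had 390 reads against 1, a depth-adjusted ratio of 362.7 (exact 95% counting interval 64.7 to 14360). CCDC85A had 403 reads against 2 (ratio 187, 51.5 to 1553), KLHDC7B 339 against 4 (78.8, 30.5 to 291) and NTNG1, an axon guidance protein, 176 against 3 (54.6, 18.4 to 267). In the other direction CXCL10 had 0 reads in sgControl and 238 in sgPRKCI, at least 30.8-fold higher, and IDO1, which degrades tryptophan, 0 and 295, at least 37.7-fold higher. These were the genes besides CXCL9 and GBP5 with a mean of at least 50 in a group and at most 3 reads in each library of the other.

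Genes higher in sgPRKCI were grouped by position. The 217 tested genes of chromosome 18 had a median log2 fold change of 0.28, or 1.22-fold, with 96 higher and 10 lower, against random sets of genes (permutation p = 0.0001, the smallest that 10000 draws can give, adjusted p = 0.0012). This test passed 0.05 for 8 of 23 chromosomes, 4 with a median above 0 and 4 below, chromosome 12 at the same p but with a median of 0.06, the next largest in size. Across 14752 pairs of neighbouring tested genes, fold changes correlated (Spearman 0.174, highest of 1000 shuffled orders 0.0266; across genes, which are not independent replicates). A trend on GC content and length was argued against as the whole cause for chromosome 18, since its median was 0.27 after correction. Of the 4 chromosomes below 0, the medians of 16, 17 and 22 became -0.01, -0.01 and 0. The median of chromosome 2 moved further from 0, from -0.0241 to -0.0367. Both arms of chromosome 18 shifted, by 0.29 (64 genes) and 0.28 (153 genes), so a gain of the whole chromosome in part or all of the sgPRKCI cells is a candidate explanation, with DNA copy number not analysed here.

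A set of genes induced by interferon gamma, CXCL9, CXCL10, IDO1, GBP1, GBP4 and GBP5, was near 0 in sgControl and present in all 3 sgPRKCI libraries, with sgPRKCI 1 at a median of 0.448 times the mean of the other two, against 0.949 for 230 other genes that rose at least 2-fold. MHC class I genes did not double as a list: their median log2 fold change was 0.03, with an upper 95% bootstrap bound of 0.39. That bound covers the spread between genes of the list, not between libraries. The bar of a doubling was set after the values were seen. A weaker interferon response, or one in part of the cells, was therefore not addressed. RNA from leukocytes in the sgPRKCI libraries cannot be told apart from induction in the LNCaP cells, since the values point both ways. Of 28 other leukocyte transcripts, 6 (21.4%, exact interval 8.30% to 40.95%) had all sgPRKCI libraries above all sgControl libraries, against 18.2% of all genes in that range of levels. For those 6 the same ratio of sgPRKCI 1 had a median of 0.766, which mixes different patterns. LCP1 (1607, 1578 and 1576 in sgPRKCI 1 to 3) and PIK3AP1 (196.4, 184.2 and 167.8) were highest in sgPRKCI 1. CD83 (76.54, 93.35 and 84.47) was lowest there. So were CCR1 (6.185, 13.69 and 17.55), IL10RA (9.278, 11.2 and 16.46) and FCGR1A (17.78, 18.67 and 39.49), all at low levels. The median level of the list was 17.05 in sgControl and 16.85 in sgPRKCI. In sgPRKCI 1 several members were below every sgControl library, among them HCLS1 (4.64, against 14.7 to 22.9) and CD4 (3.87, against 11.96 to 14.9). Of the 28, 8 more, SPI1, LAPTM5 (41.2 to 50.5 in sgControl, then 31.7, 82.2 and 143) and CYBB (26.6 to 41.9, then 31.7, 75.9 and 99.8) among them, were above sgControl in sgPRKCI 2 and 3 but not in sgPRKCI 1, while VSIG4 and CD4 were not, and outside the list the macrophage complement genes C1QA, C1QB and C1QC, picked after the data had been seen, rose by 2.00, 1.74 and 2.13 on the log2 scale.

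The rise of ribosomal protein genes was weighed in the same way. A trend on GC content and length was argued against, with a list median of 0.36 after correction, and so was the scaling of the libraries, where the lower of the medians under TMM factors and quantile normalization was 0.26. A hypothesis is that transcripts with a 5' TOP motif, a sequence through which mTORC1 acts on translation and on the stability of messages, rose as a class. In a list of 30 tested non-ribosomal 5' TOP transcripts 21 rose and 1 fell, with a median of 0.25 (camera p = 7.33e-13, and p = 0.0172 with an estimated correlation) and 0.21 under quantile normalization; 7 of the 30 belong to lists already seen, and the others had a median of 0.25. Another difference between the cell populations stays open, since no label names more than 1 population per guide and the chromosome 18 median of 0.28 is a mark of such a difference.

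Splitting the 6 libraries into 3 and 3 in all 10 ways gives too few splits for a share under 0.05. The real split gave 4404 genes changed (2123 higher, 2281 lower), and the highest of the others 0, so that 1 of the 10 splits reached each of these counts. Camera called 8 lists higher and 4 lower in the real split and up to 10 in a single direction in others: 2 of the 10 splits gave at least 8 in a direction and 4 gave at least 4. Each of the other splits kept part of the guide difference between its sides and put the rest into the spread within them, so these counts are not what an absence of any effect would give: limma was bound to call few genes, and camera could still call lists that the guides moved.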
